A study of Mus musculus with 141 samples.

How the data were processed

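The deposited tables hold raw read counts per gene, a unit read from the file names, the whole-number values and the tools the labels list. The tables of dorsal lateral geniculate nucleus (dLGN) and visual cortex (VC) at postnatal day (P) 30 and after the light exposure of young mice count reads over exons. The VC table of 8-week-old mice counts reads over gene bodies, which adds introns, according to its file name. Between WT libraries at 0 h of this table and of the VC light table, over 11403 genes, CPM had a median log2 ratio of 0.517 for genes of at least 100 kb and -0.104 for shorter ones. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to the mouse genome mm10 with STAR 2.5.2b and counted with featureCounts of the Subread package, with no version given. The notes also name edgeR 3.34.1 and DESeq2 1.34.0, which left no values in these tables. Strand setting and annotation were not stated for the tables used here.

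Of 141 samples in 24 groups, 77 samples in 16 groups were used, from 5 tables. The other 64 columns, in 4 tables of dLGN and VC at P15 (n = 6 per group) and P16 (n = 10 per group), carry animal numbers without a genotype. They could not be assigned to wild-type (WT) or knock-in groups, so they were left out, and 6 of the 24 planned comparisons, with their alternatives, were not run. Columns were matched to groups by the tissue, genotype and light time in the column names. The highest Xist count in any library was 6 and the lowest Ddx3y value was 47.91 CPM (counts-per-million), as male mice should show. Each pair of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of at least 2.3.

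The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each table was fitted on its own, except that WT libraries of both tissues were fitted together to compare their light responses. Genes were filtered with edgeR's filterByExpr by group and libraries scaled by the trimmed mean of M values (TMM). Each contrast between group means was tested with edgeR's two-sided quasi-likelihood F test. The p values were adjusted over all tested genes of a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Expression is given in CPM on TMM-adjusted library sizes, as mean ± SD over the libraries of a group. Changes are log2 fold changes from edgeR at its default prior count, ± a standard error. That error was computed as the absolute log2 fold change divided by the square root of the F statistic. Values of log2 CPM used a prior count of 2. Each library came from 1 column, so n is the number of libraries in a group.

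The tables have 24500 gene symbols, or 24498 in the 8-week table. Positions are those of mm10 (GRCm38) gene annotation, found for 24423 symbols, 99.7% of them. The symbols are the only identifiers in the tables.

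The text names genes by a rule. In each comparison these are the 10 called genes with the largest rise and the 10 with the largest fall, among genes with a mean of at least 1 CPM over the libraries compared. Where no gene passed, these are the 5 genes with the smallest p, stated not to pass. Mecp2 is always given. From each gene list discussed, up to 4 members are named, called genes with the smallest adjusted p first. Dsc3 is an exception stated where it appears.

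Gene lists were tested with limma's camera, two-sided, on the edgeR counts and design with a preset correlation between genes of 0.01, and adjusted over the 24 lists of a comparison. Because genes of a list vary together between animals, every list result was recomputed with the correlation estimated from the data, and that adjusted p is given beside each list result. Members of a list were also counted by adjusting p over the list alone. The lists covered early response, late response, reported MeCP2 targets, MeCP2 and partners, glutamate receptors, GABA receptors, presynaptic and postsynaptic scaffold, refinement and complement, and markers of thalamic relay, cortical excitatory, inhibitory and hippocampal neurons. They also covered markers of oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, endothelial and mural cells, choroid plexus and ependymal cells, meningeal fibroblasts and blood, with heat shock genes, circadian clock genes, glucocorticoid response genes and ribosomal protein genes. All were written from general knowledge of these genes.

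Because MeCP2 has been linked to long genes, the median log2 fold change of genes of at least 100 kb, minus that of shorter genes, was compared between genotypes by a two-sided exact permutation test over the libraries of the compared groups. The size of the light response was summarised per library as the mean log2 CPM of genes that rose with 4 h of light minus that of genes that fell. These genes were called in the same tissue on the average of both genotypes, and the VC genes served the 8-week table too.

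The alternatives were DESeq2's size factors in place of TMM, no filter on low counts, DESeq2's Wald test, an estimated correlation for the lists, 60 kb for long genes, long genes with a mean of at least 5 CPM, and leaving out each library of the light experiments in turn. A block for the replicate number was used for the 8-week table. Columns of the other tables carry animal numbers in place of replicate numbers, so their block rests on inferred sets, chosen after seeing the data. At P30 animals 1 to 12 follow the titles in accession order by genotype, and each took the replicate number of the title at its place. In the light experiment a set was the place of the column within its group. The same numbers appear in the dLGN and VC tables, with the same genotype and light time for 12 of 12 at P30 and 16 of 16 in the light experiment, so both tissues were taken to come from the same animals. In the light experiment deviations from the group means of the 2 tissues of an animal correlated at a mean of 0.113 (-0.028 to 0.336), against -0.037 for other animals of the group. At P30 the means were 0.101 and -0.02. The fit of both tissues was therefore repeated with the animal as a block, an alternative chosen after seeing the data. The number of called genes was also recounted under other splits of the same libraries, at most 100 per comparison, drawn with seed 1. Groups, comparisons, tests, gene lists, the naming rule and alternatives were choices made before the data were examined, except for the alternatives and tests stated in the closing section to have come later.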

Results

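RNA was measured by sequencing of total RNA, after removal of ribosomal RNA, in dLGN and VC of male C57BL/6 mice. This follows the extraction protocol, which describes whole tissue, while the design text speaks of nucleus RNA for P15, P16 and P30. The dLGN is the thalamic relay that passes signals from the retina to VC. WT mice were compared with littermates that carry 1 of 2 changes in Mecp2, the gene of a methyl-DNA-binding protein mutated in Rett syndrome that gains phosphate groups when neurons fire. QKI is a knock-in whose changed sites the labels do not list. T308A is a knock-in that puts alanine in place of a threonine. The series title frames the question as whether phosphorylation of MeCP2 by neuronal activity regulates the refinement of synapses between retina and dLGN.

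Mice at P30 (labelled P30 or P31) gave 4 groups of 6 libraries, WT and QKI in dLGN and in VC. In the light experiment of young mice, WT and QKI mice lived without light between P20 and P30 by the design text (the labels give P27) and then received 0 h or 4 h of light. It gave 8 groups of 4 libraries, 4 in each tissue. In the experiment at 8 weeks, mice spent the weeks between ages 6 and 8 weeks in darkness and received 0 h or 6 h of light, and only VC was taken. Its groups had 3 WT and 3 T308A libraries at 0 h, and 5 WT and 10 T308A libraries at 6 h.

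Total counts per library, in mega-counts (M), ran from 11.3 to 19.2 M in dLGN at P30 and from 11.8 to 20.5 M in VC at P30. They ran from 7.47 to 12.2 M in dLGN and from 5.4 to 11.1 M in VC of the light experiment. They ran from 15.4 to 21 M at 8 weeks. Between 16536 and 17678 genes were detected per library. The P30 dLGN groups differed in depth, with 17.5 ± 1.57 M counts in WT and 13.9 ± 2.15 M in QKI (SD, n = 6), which the scaling takes into account.

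Mecp2 itself (chromosome X, 74026592 to 74085690) was expressed in every group, between 202 and 304 CPM per library, and no edgeR comparison called it. Its log2 fold changes lay between -0.10 and 0.08. The lowest was with 6 h of light in WT at 8 weeks (-0.10 ± 0.042, adjusted p = 0.0908). No difference in its RNA between genotypes was detected, for example 234 ± 12.4 CPM in WT and 235 ± 10.1 CPM in QKI dLGN at P30 (SD, n = 6).

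**Figure D1:**
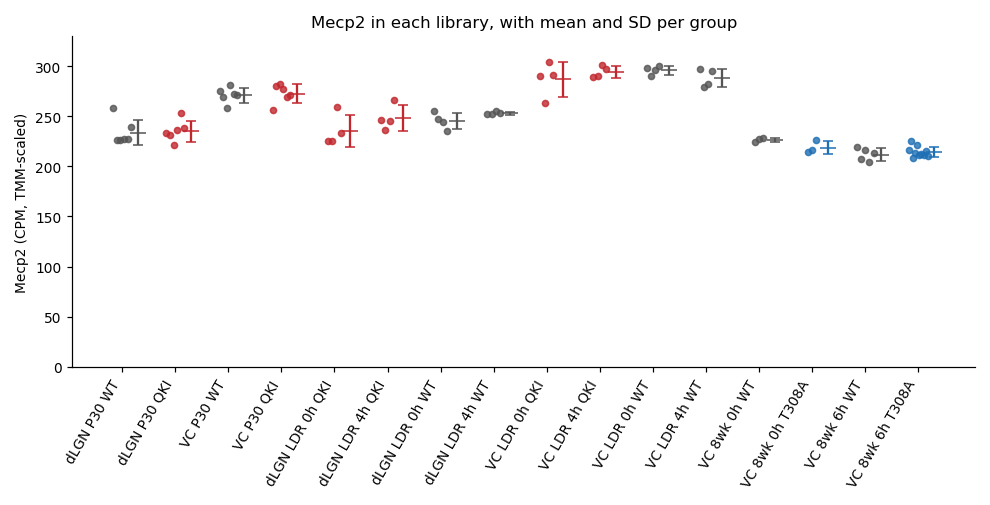
Mecp2 in CPM per library (points) in the 16 groups used, with the mean and SD of each group as a bar. Every library lies between 202 and 304 CPM, and mutant and WT points overlap at each age and light time.

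The contrasts of light after darkness called at least 579 genes in each tissue and genotype, while the contrasts with a genotype term called few genes or none. Clock genes moved in every light comparison, at percentiles from 99.3 to 99.9 of random gene lists matched on expression. A different time of day at collection may therefore contribute to the light calls, and the design cannot separate it from light.

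**Figure D2:**
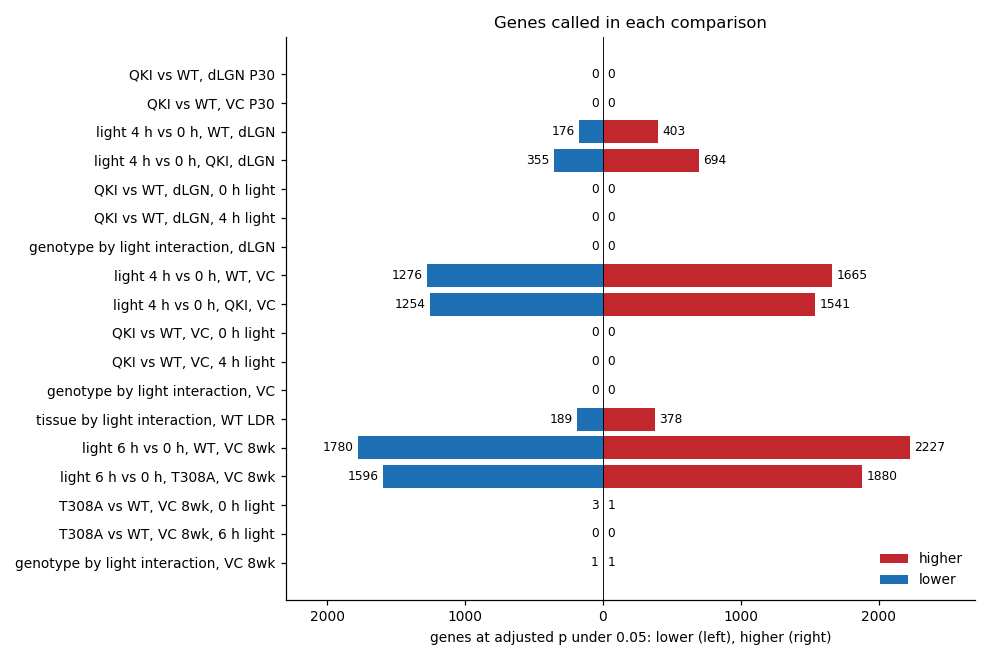
Number of genes called at an adjusted p below 0.05 in each of the 18 comparisons, with rises and falls as separate bars. The 6 light comparisons call between 579 and 4007 genes, tissue by light calls 567, and the comparisons with a genotype term call at most 4.

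The first question was which genes light switches on in WT dLGN. Fosb (chromosome 7, 19302696 to 19310118), an immediate early gene, rose by log2 5.49 ± 0.484 (adjusted p = 4.54e-07), from 0.247 ± 0.148 CPM at 0 h to 11.4 ± 3.47 CPM at 4 h (SD, n = 4). The early response genes Egr3 (2.70 ± 0.193, adjusted p = 4.01e-08) and Fos (2.29 ± 0.298, adjusted p = 4.37e-05) rose too. Genes that glucocorticoids induce rose as well. Cdkn1a (chromosome 17, 29090979 to 29100722), a cell cycle inhibitor, went from 2.99 ± 0.594 to 28.1 ± 8.92 CPM (3.22 ± 0.243, adjusted p = 4.57e-08). Zbtb16 (chromosome 9, 48651797 to 48836225), a transcription factor, went from 15.7 ± 2.23 to 71.9 ± 20.1 CPM (2.20 ± 0.215, adjusted p = 1.3e-06).

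In all, 403 genes rose and 176 fell of 14136 tested in WT dLGN. The other largest rises were Mir6236 (3.19), Plin4, a lipid droplet gene (2.87), Map3k6 (2.38), Hif3a, a hypoxia-inducible factor (2.33), and Cldn1, a tight junction gene (2.13). Among the falls, Mmp14, a matrix protease, went from 28.7 ± 1.31 to 13.2 ± 1.79 CPM (-1.13 ± 0.115, adjusted p = 2.12e-06). Falls of Aplnr (-1.46), Rab38 (-1.41), Ptger4 (from 7.36 to 3.69 CPM) and Dnah2 (from 5.88 to 2.96 CPM) also kept their calls whichever library was left out. The remaining falls were Nmur1 (-1.29), Cxcr4 (-1.26), Fbxo40 (-1.14), Adamts12 (-1.05) and Slc2a10 (-0.99). Of these 20 genes, 7 lost the call without some single library. The highest adjusted p were 0.211 for Mir6236 without LGN13 (log2 1.91), 0.0927 for Cldn1 and 0.0628 for Cxcr4 without LGN16, 0.0951 for Nmur1 and 0.138 for Slc2a10 without LGN5. They were 0.0819 for Fbxo40 without LGN8 and 0.0996 for Adamts12 without LGN11. Mecp2 did not change (0.05 ± 0.05, adjusted p = 0.75).

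Among gene lists in WT dLGN, 17 of 25 early response genes rose and 1 fell over all genes (20 and 1 adjusted over the list alone), with a median log2 of 1.307 and an adjusted p = 0.000249 with an estimated correlation. Members were Egr1 (1.33 ± 0.122) and Fosl2 (2.04). Of 25 late response genes 10 rose by either count (adjusted p = 0.000249 with an estimated correlation), with Tnfrsf12a (1.67), Vgf (0.79) and Bdnf (1.06), a growth factor of neurons. Of 12 glucocorticoid response genes 9 rose over all genes and 11 over the list alone (adjusted p = 0.000632 with an estimated correlation), among them Fkbp5 (1.49), Tsc22d3 (0.88) and Sgk1 (0.62 ± 0.108, adjusted p = 0.00123). Of 21 reported MeCP2 targets 5 rose over all genes, and 6 rose and 1 fell over the list alone (adjusted p = 0.00413 with an estimated correlation), among them Prodh (0.68). The glucocorticoid list shares 2 genes with the reported MeCP2 targets and 1 each with the early and late response lists. Results of these lists are therefore not independent, in any comparison.

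A further 4 lists passed only with the preset correlation. Of 23 refinement and complement genes 4 rose by either count, among them Mertk (1.10), with an adjusted p = 0.123 with an estimated correlation. Of 11 heat shock genes 4 rose over all genes and 6 over the list alone, among them Hspa1b (1.61), with an adjusted p = 0.123 with an estimated correlation. Meningeal fibroblast markers had a median of -0.386 and blood markers of 0.6, with no member called and an adjusted p = 0.431 with an estimated correlation for each.

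The same light exposure in QKI dLGN asked whether the response persists in mice with the changed sites. Fosb went from 0.34 ± 0.198 to 14.2 ± 7.08 CPM (5.31 ± 0.438, adjusted p = 6.55e-08; SD, n = 4). Cdkn1a rose from 3.46 ± 0.451 to 37.8 ± 9.35 CPM (3.45 ± 0.231, adjusted p = 1.05e-08). Egr3 (2.67 ± 0.185, adjusted p = 1.05e-08) and Zbtb16 (2.25 ± 0.207, adjusted p = 3.64e-07) rose as well.

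In QKI dLGN 694 genes rose and 355 fell. Plin4 (3.51, or 4.50 without LGN9), Tekt4 (2.85), Egr4 (2.51), Fosl2 (2.33), Map3k6 (2.24) and Ttr (3.95), a choroid plexus gene, complete the largest rises. Falls were Adamts12 (-1.55), Rab38 (-1.37), Wnt5b (-1.31), Adgrd1 (-1.22), Foxb1 (-1.22), Gbp4 (-1.49), Hist1h1a (-1.31), Tnfsf10 (-1.14), Mir6236 (-3.31) and Lars2 (-2.46), a mitochondrial tRNA ligase. The call of Ttr rested on library LGN3, without which its log2 was -0.14 (adjusted p = 0.934). Those of Mir6236 (-2.06, adjusted p = 0.107) and Lars2 (-1.48, adjusted p = 0.0796) ended without LGN4. Gbp4 (adjusted p = 0.052) and Tnfsf10 (adjusted p = 0.16) lost theirs without LGN10, and Hist1h1a (adjusted p = 0.0584) without LGN9. Mecp2 did not change (0.08 ± 0.05, adjusted p = 0.428).

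The 4 lists that passed with either correlation in WT dLGN passed in QKI too. Early response genes rose in 18 of 25 cases over all genes, and 20 rose and 1 fell over the list alone (adjusted p = 0.000244 with an estimated correlation). Of 25 late response genes 10 rose over all genes, and 14 rose and 1 fell over the list alone (adjusted p = 0.000237 with an estimated correlation). Of 12 glucocorticoid response genes 11 rose by either count, led by Sgk1 (1.16, adjusted p = 3.8e-07) and Nfkbia (1.24), with an adjusted p = 0.000244 with an estimated correlation. Of 21 reported MeCP2 targets 6 rose by either count (adjusted p = 0.00152 with an estimated correlation), among them Igfbp3 (0.78). Of 11 heat shock genes 5 rose over all genes and 9 over the list alone (adjusted p = 0.0273 with an estimated correlation), among them Hsph1 (0.46).

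Passing with the preset correlation alone were 3 more lists in QKI dLGN. Of 16 clock genes 3 rose and 2 fell over all genes, and 6 rose and 2 fell over the list alone (adjusted p = 0.176 with an estimated correlation). Of 13 cortical excitatory markers 2 fell by either count, with a median of -0.139 (adjusted p = 0.526 with an estimated correlation). Of 10 meningeal fibroblast markers none fell over all genes and 1 over the list alone (adjusted p = 0.686 with an estimated correlation). WT and QKI dLGN shared 345 rises, where 19.8 would be shared by independent lists, and 111 falls, against 4.4. Opposite directions were called for 2 genes.

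In WT VC, light raised Fosb from 5.96 ± 4.13 to 95.1 ± 31.7 CPM (4.02 ± 0.342, adjusted p = 2.62e-07; SD, n = 4). Nptx2 (chromosome 5, 144545887 to 144557478), a pentraxin that gathers glutamate receptors at synapses, rose from 22.1 ± 3.93 to 286 ± 107 CPM (3.70 ± 0.299, adjusted p = 2.15e-07). Arc (chromosome 15, 74669081 to 74672570), which acts at active synapses, rose from 84.2 ± 44 to 808 ± 478 CPM (3.27 ± 0.456, adjusted p = 4.68e-05). Ptgs2, a prostaglandin synthase of active neurons, rose from 10.5 ± 2.45 to 125 ± 62.2 CPM (3.57 ± 0.318, adjusted p = 4e-07).

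In WT VC 1665 genes rose and 1276 fell of 14106 tested. The other largest rises were Inhba (3.65), Cdkn1a (3.28), Car12 (3.23, or 3.88 without CTX11), Pim1 (3.21), Slc23a3 (3.15) and Plekhg4 (3.13). Ankfn1 (chromosome 11, 89390092 to 89777901) fell from 15.7 ± 2.62 to 5.86 ± 0.985 CPM (-1.43 ± 0.153, adjusted p = 2.58e-06). Rnf207 (-1.65), Gm5148 (-1.54), B3gnt7 (-1.47) and Cdh15 (-1.32) fell and kept their calls whichever library was left out. Falls of Gpr6 (-1.42) and Cyp26b1 (-1.37) were lost without CTX5, at -1.04 (adjusted p = 0.0688) and -0.96 (adjusted p = 0.0624). Those of Apol7a (-1.37, or -2.51 without CTX8; adjusted p = 0.0985) and Iigp1 (-1.32; adjusted p = 0.0543) were lost without CTX1, and that of Catsperg1 (-1.31; adjusted p = 0.109) without CTX13. Mecp2 did not change (-0.04 ± 0.046, adjusted p = 0.602).

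Late response genes rose in 25 of 26 cases by either count in WT VC, with a median log2 of 1.443 (adjusted p = 0.0122 with an estimated correlation). Bdnf (2.99, adjusted p = 4e-07), Crh (2.31) and Pcsk1 (1.84) were among them. Of 12 glucocorticoid response genes 9 rose by either count (adjusted p = 0.00495 with an estimated correlation), with Fkbp5 (1.49), Mt2 (1.22), Tsc22d3 (1.08) and Zbtb16 (1.02 ± 0.087, adjusted p = 2.62e-07). Early response genes rose in 24 of 25 cases over all genes, and 24 rose and 1 fell over the list alone, with a median of 1.726. Their list test gave an adjusted p = 0.0698 with an estimated correlation.

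Passing with the preset correlation alone were 3 other lists in WT VC. Of 15 inhibitory neuron markers 6 rose over all genes and 7 over the list alone, among them Penk (1.03), Vip (0.44) and Gad1 (0.35), with an adjusted p = 0.441 with an estimated correlation. Of 28 scaffold genes 8 rose over all genes and 9 over the list alone, among them Nrxn2 (0.46) and Gphn (0.29), with an adjusted p = 0.845 with an estimated correlation. Of 11 heat shock genes 6 rose over all genes and 7 over the list alone, among them Hsph1 (0.89) and Hspa8 (0.64), with an adjusted p = 0.206 with an estimated correlation.

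In QKI VC, Fosb rose from 3.78 ± 1.98 to 70.9 ± 25.9 CPM (4.22 ± 0.367, adjusted p = 5.9e-07; SD, n = 4). Arc rose from 58.3 ± 34.3 to 707 ± 321 CPM (3.60 ± 0.467, adjusted p = 2.58e-05), and Nptx2 from 27.7 ± 10.3 to 247 ± 97.1 CPM (3.16 ± 0.289, adjusted p = 6.94e-07). Ankfn1 fell from 16.4 ± 2.65 to 5 ± 0.624 CPM (-1.72 ± 0.158, adjusted p = 6.94e-07).

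In QKI VC 1541 genes rose and 1254 fell. Further large rises were Egr2 (3.55), Car12 (3.41), Rasd1 (3.28), Inhba (3.27), Cdkn1a (3.18), Ptgs2 (3.10) and Fos (2.91). Further falls were Gm12216 (-1.99), Gm5148 (-1.96), Tshr (-1.67), Col8a1, a collagen (-1.53), Mrap2 (-1.47), Fgl2 (-1.41) and Fgfbp1 (-1.41). Abcc6 (-1.83, or -2.76 without CTX2) was lost without CTX12 (-1.44, adjusted p = 0.0528) and Asgr1 (-1.41) without CTX10 (-1.27, adjusted p = 0.114). Mecp2 did not change (0.03 ± 0.046, adjusted p = 0.649).

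Among lists in QKI VC, late response genes rose in 24 of 26 cases over all genes and in 26 over the list alone (adjusted p = 0.0235 with an estimated correlation). Of 12 glucocorticoid response genes 9 rose over all genes and 10 over the list alone (adjusted p = 0.0013 with an estimated correlation). Early response genes rose in 22 of 25 cases over all genes and 23 over the list alone (adjusted p = 0.0757 with an estimated correlation). Of 16 oligodendrocyte markers 8 rose over all genes and 10 over the list alone, among them Mobp (0.93), Ermn (0.63) and Ugt8a (0.46), with an adjusted p = 0.611 with an estimated correlation. The same adjusted p = 0.611 with an estimated correlation held for 9 oligodendrocyte precursor markers, of which 5 rose by either count, and for 10 meningeal fibroblast markers, of which 3 fell over all genes and 9 over the list alone. Of 11 heat shock genes 5 rose by either count (adjusted p = 0.201 with an estimated correlation).

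WT and QKI VC shared 1073 rises (181.9 for independent lists) and 663 falls (113.4), and no gene was called in opposite directions. WT dLGN and WT VC shared 216 rises (47.4) and 59 falls (15.1), in libraries of the same animals. Between tissues, 6 genes that rose in dLGN fell in VC, and 14 that fell in dLGN rose in VC.

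**Figure D3:**
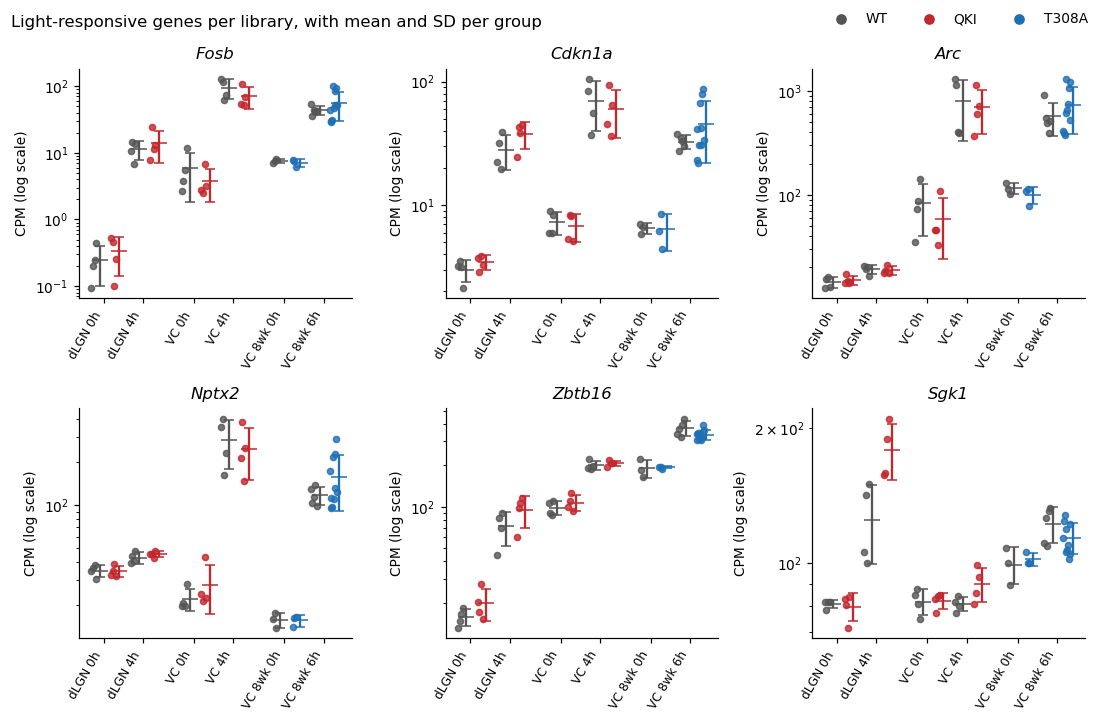
CPM per library on a log axis for Fosb, Cdkn1a, Arc, Nptx2, Zbtb16 and Sgk1, in darkness and after light, for dLGN and VC of young mice (0 h and 4 h) and VC at 8 weeks (0 h and 6 h). WT is grey, QKI red and T308A blue. Arc and Nptx2 rise in VC, Nptx2 to a mean of 286 CPM in WT at 4 h, while in WT dLGN at 4 h they reach means of 19.2 and 42.9 CPM.

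The tissues, taken from the same animals by the numbers of the columns, were compared directly in WT by the difference between the VC and dLGN light responses. Nptx2 rose more in VC by log2 3.40 ± 0.283 (adjusted p = 6.55e-07). It went from 21.8 ± 3.86 to 283 ± 107 CPM in VC, and from 35.3 ± 3.55 to 43.5 ± 3.98 CPM in dLGN (SD, n = 4). Arc responded more in VC as well (2.86 ± 0.564, adjusted p = 0.00419), with 14.6 ± 1.79 and 19.5 ± 1.95 CPM in dLGN at 0 h and 4 h. In the other direction, Car7 (chromosome 8, 104534694 to 104550347), a carbonic anhydrase, rose more in dLGN, from 10.5 ± 1.48 to 34.2 ± 5.54 CPM against 17.9 ± 1.76 to 19.6 ± 1.83 CPM in VC (-1.57 ± 0.173, adjusted p = 2.23e-05).

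The log2 change with light was higher in VC than in dLGN for 378 genes and lower for 189, of 14328 tested. Other positive differences were Ptgs2 (3.86), Wnt9b (3.80, or 4.75 without CTX5), Inhba (3.52), Pim1 (3.39), Adgrd1 (3.06), Rasl11a (2.75), Rasd1 (2.63) and Lipg (2.29). Negative differences, which include falls in VC, were Pth2r (-2.06), Stc1 (-1.86), Ankfn1 (-1.75; from 15.5 to 5.8 CPM in VC), Mettl18 (-1.56), Mir6236 (-2.96), Amn (-2.20), Rnf207 (-1.77), Tacr3 (-1.72) and Cldn1 (-1.53). The calls of 8 of these 20 genes ended without some single library. The highest adjusted p were 0.0624 for Ptgs2 and 0.0792 for Inhba without LGN5, 0.135 for Lipg and 0.0654 for Cldn1 without LGN16, and 0.104 for Mir6236 without LGN7. Mir6236 was at -1.68 without LGN13 (adjusted p = 0.102). They were 0.0968 for Amn without LGN8, 0.0789 for Rnf207 without CTX13 and 0.12 for Tacr3 without LGN6. Mecp2 did not differ (-0.08 ± 0.065, adjusted p = 0.605).

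By list, 15 of 26 late response genes had a higher log2 change in VC over all genes, and 19 a higher and 1 a lower one over the list alone (adjusted p = 0.034 with an estimated correlation), among them Sorcs3 (1.42), Nrn1 (1.09) and Scg2 (1.38). Of 25 early response genes 7 had a higher one by either count, among them Ier5 (1.38) and Dusp6 (1.37), with an adjusted p = 0.924 with an estimated correlation. The labels give less input RNA for dLGN libraries than for VC libraries, so library preparation differs along with tissue.

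At P30 the question was whether QKI alters gene expression in mice under no light schedule. In dLGN, edgeR called no gene of 14207 tested (202 at an unadjusted p under 0.05), and DESeq2 called 0. The smallest p were those of Rbm47 (-0.86 ± 0.21), an RNA-binding protein at 0.656 ± 0.176 CPM in QKI and 1.23 ± 0.161 CPM in WT (SD, n = 6), Phf19 (-0.88), Ifit3b (-0.54), Nlrp5-ps (0.56) and Ptk7 (-0.28). None passed (adjusted p = 1). With the replicate block of inferred sets, chosen after seeing the data, Nlrp5-ps alone passed (0.70, adjusted p = 0.033). Mecp2 was level (0.01 ± 0.046, adjusted p = 1).

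At P30 in dLGN 3 lists passed with the preset correlation, none with a member called. Of 24 early response genes 3 were higher in QKI, with a median of -0.096. Of 16 oligodendrocyte markers 15 were higher, with a median of 0.046, and 1 of 10 meningeal fibroblast markers was higher, with a median of -0.25. Each of these had an adjusted p = 0.991 with an estimated correlation. A self-test on simulated counts with the depth and dispersion of these libraries recovered 86.4% of genes changed 1.5-fold in this comparison, 57 of 66, with 8 false calls. The simulation changed many genes at once and drew each gene independently. Recovery may be lower where fewer genes change or where genes vary together between animals, and that was not simulated.

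In VC at P30, edgeR called no gene of 14228 tested (645 at an unadjusted p under 0.05), and DESeq2 called 0. The smallest p (adjusted p = 0.985) were those of Nek2 (-1.14), Matn2, a matrix protein (0.43 ± 0.095; 29.5 ± 3.97 CPM in QKI and 21.9 ± 2.62 CPM in WT; SD, n = 6), Bach2 (0.42), Nos1, the neuronal nitric oxide synthase (0.41), and Arrdc1 (0.42). Mecp2 was level (0.01 ± 0.039, adjusted p = 0.998).

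Activity genes leaned down and oligodendrocyte markers up in QKI VC at P30, without any member called. Only 1 of 24 early response genes was higher in QKI (median -0.267, Egr1 -0.29 and Egr2 -0.75), and 3 of 26 late response genes (median -0.121, Rgs4 -0.23). Their list tests had an adjusted p = 0.512 and an adjusted p = 0.486 with an estimated correlation. All 16 oligodendrocyte markers were higher (median 0.175, Gpr37 0.25 and Mobp 0.24; adjusted p = 0.512 with an estimated correlation). The other lists past the preset threshold were scaffold genes (median -0.041; adjusted p = 0.512 with an estimated correlation), oligodendrocyte precursors (0.117) and blood markers (0.201), each with an adjusted p = 0.546 with an estimated correlation, choroid plexus markers (0.41; adjusted p = 0.455 with an estimated correlation) and meningeal fibroblast markers (0.288; adjusted p = 0.601 with an estimated correlation). The QKI library CTX9 stood apart in Wfs1, a hippocampal marker, at 131.2 CPM against 41.46 to 54.46 CPM in the other VC libraries at P30. The self-test recovered 78.8% of genes changed 1.5-fold.

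In dark-reared dLGN (0 h), edgeR called no gene between QKI and WT (300 at an unadjusted p under 0.05; DESeq2 called 0). The smallest p (adjusted p = 1) were those of Lars2 (2.51; 384 ± 387 CPM in QKI and 67.6 ± 6.24 CPM in WT; SD, n = 4), Mir6236 (3.59), Esrrg, a nuclear receptor (0.33; 50.4 ± 1.48 and 40.1 ± 2.87 CPM), Sv2c, a synaptic vesicle gene (0.68), and Ubxn10 (-1.85). Lars2 and Mir6236 were highest in LGN4, at 950.3 and 329.7 CPM. Mecp2 was level (-0.06 ± 0.05, adjusted p = 1), and no list passed.

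After 4 h of light in dLGN, edgeR called no gene between QKI and WT (556 at an unadjusted p under 0.05), and DESeq2 called 1. That gene was Sgk1 (chromosome 10, 21882184 to 21999903), a kinase induced by glucocorticoids. It stood at 179 ± 25.6 CPM in QKI and 125 ± 25.1 CPM in WT (0.52 ± 0.105; SD, n = 4), with an adjusted p = 0.644 in edgeR and an adjusted p = 0.0289 in DESeq2. The next smallest p were those of Gm13629 (0.45, adjusted p = 0.644), Slc2a13 (0.20), Peli2 (0.27) and Gfra1 (0.23, adjusted p = 1 for each). Mecp2 was level (-0.03 ± 0.05, adjusted p = 1). All 12 glucocorticoid response genes were higher in QKI, with a median of 0.347, none called over all genes and 2 over the list alone, with an adjusted p = 0.136 with an estimated correlation. Nfkbia (0.40), Cdkn1a (0.42) and Ddit4 (0.24) were among them.

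Whether light acts differently in QKI dLGN was tested by the interaction. It called no gene in edgeR (383 at an unadjusted p under 0.05), and 2 in DESeq2. These were Mir6236 (-6.50 ± 1.168; adjusted p = 0.12 in edgeR, 0.00529 in DESeq2) and Lars2 (-4.49 ± 0.817; adjusted p = 0.12 in edgeR, 0.0255 in DESeq2). Both rest in part on LGN4 (QKI, 0 h) and LGN13 (WT, 4 h). The 2 genes were high together, Mir6236 and Lars2 at 329.7 and 950.3 CPM in LGN4 and 251.3 and 648.4 CPM in LGN13. They were low together in LGN15 (6.331 and 49.85 CPM), and high together in VC library CTX8 at P30 (203.2 and 509 CPM). The cause of this shared variation between libraries was not tested. Mir6236 was at -5.25 without LGN4, -5.22 without LGN13 and -3.96 without both, and Lars2 at -3.52, -3.62 and -2.64 (adjusted p = 0.19 for each without both). Then followed Vash2 (0.45), Mlec (0.25) and Mettl18 (-1.25), each with an adjusted p = 1. Mecp2 did not differ (0.03 ± 0.071, adjusted p = 1). With the preset correlation 6 lists passed, with no member called over all genes. Their medians were 0.233 for glucocorticoid response genes, with 12 of 12 positive and 1 called over the list alone, 0.142 for heat shock genes, 0.055 for thalamic relay markers and -0.125 for refinement and complement genes, each with an adjusted p = 0.488 with an estimated correlation. Microglia markers (-0.176) and choroid plexus markers (1.586) had an adjusted p = 0.579 with an estimated correlation. The choroid plexus median came from LGN3 and was -0.102 without it.

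In dark-reared VC (0 h), edgeR called no gene between QKI and WT (403 at an unadjusted p under 0.05; DESeq2 called 0). The smallest p (adjusted p = 1) were those of Mir6236 (1.06), Myo19, a mitochondrial myosin (-0.41; SE 0.099), Phkb (-0.27), Lars2 (0.66) and Adi1 (-0.37). Mecp2 was level (-0.04 ± 0.046, adjusted p = 1). With the preset correlation 6 lists passed, with no member called. Early response genes had a median of -0.183 (adjusted p = 0.826 with an estimated correlation). Scaffold genes (0.037), inhibitory markers (0.094), oligodendrocyte precursors (-0.086), astrocytes (-0.069) and endothelial and mural cells (-0.123) each had an adjusted p = 0.798 with an estimated correlation.

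After 4 h of light in VC, edgeR called no gene between QKI and WT (852 at an unadjusted p under 0.05; DESeq2 called 0). The smallest p (adjusted p = 0.81) were those of Dact2, a regulator of Wnt signalling (-0.34 ± 0.071; 61.3 ± 4.47 CPM in QKI and 77.9 ± 7.84 CPM in WT; SD, n = 4), Npsr1 (1.32), Praf2 (-0.34), Trim12a (-1.15) and Fat3 (0.24). Without CTX2, Npsr1 passed (1.59, adjusted p = 0.0179). Mecp2 was level (0.03 ± 0.046, adjusted p = 0.938). All 16 oligodendrocyte markers were higher in QKI (median 0.279), with 3 called over the list alone, none over all genes, and an adjusted p = 0.636 with an estimated correlation. Plp1, a myelin gene, stood at 932 ± 85 CPM in QKI and 703 ± 143 CPM in WT (0.41), with Ermn (0.49) and Ugt8a (0.36) moving alike. The other lists past the preset threshold had an adjusted p = 0.819 with an estimated correlation. Their medians were -0.265 for early response, -0.127 for late response, -0.461 for meningeal fibroblast, -0.932 for blood, of which 5 of 6 were called over the list alone, and -0.065 for ribosomal protein genes.

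The interaction in VC called no gene in edgeR (693 at an unadjusted p under 0.05), and 0 in DESeq2. The smallest p (adjusted p = 0.964) were those of Dact2 (-0.40), Zfp868 (0.47), 1700001L05Rik (-0.64), Fam120aos (0.55) and Phkb (0.37). Mecp2 did not differ (0.07 ± 0.065, adjusted p = 0.977). Oligodendrocyte markers (median 0.237), oligodendrocyte precursors (0.154) and late response genes (-0.131) passed with the preset correlation, with an adjusted p = 0.773 with an estimated correlation for each and no member called. For genes changed 1.5-fold the self-test recovered 52.2% in the dLGN interaction and 54.5% in the VC interaction. Changes of that size were thus missed about as often as found in the simulation.

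A shift of genes of at least 100 kb against shorter ones was not detected in most contrasts, by two-sided exact permutation tests. The shift was log2 0.0144 (p = 0.576) in dLGN and -0.0025 (p = 0.894) in VC at P30. It was 0.0102 (p = 0.629) at 0 h and 0.0149 (p = 0.314) at 4 h in dLGN, and 0.0032 (p = 0.8) at 0 h in VC. At 4 h in VC it was 0.0221 with an exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow. That p was not adjusted for the 8 shifts tested. For T308A at 8 weeks the shift was 0.1288 at 0 h (exact permutation p = 0.3, with 0.1 the smallest possible) and -0.0486 at 6 h (exact permutation p = 0.312).

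In WT VC at 8 weeks the question was which genes 6 h of light changes. Egr1 (chromosome 18, 34861207 to 34864956) rose from 72 ± 6.78 CPM (SD, n = 3) to 389 ± 85.6 CPM (SD, n = 5), by 2.43 ± 0.271 (adjusted p = 5.56e-06). Npas4, a transcription factor specific to neuronal activity, rose from 4.77 ± 0.801 to 41.2 ± 13 CPM (3.10 ± 0.425, adjusted p = 3.53e-05), and Nptx2 from 15.9 ± 1.85 to 117 ± 16.7 CPM (2.88 ± 0.335, adjusted p = 7.6e-06). Smpdl3b, a phospholipase of membranes, fell from 2.18 ± 0.245 to 0.631 ± 0.161 CPM (-1.79 ± 0.284, adjusted p = 0.000125).

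In WT at 8 weeks 2227 genes rose and 1780 fell of 15049 tested (2356 calls without WT 0 h replicate 1). Egr2 (3.97), Mir212 (2.92), Ptgs2 (2.76), Fos (2.68), Inhba (2.60), Fosb (2.52) and Nr4a1 (2.45) were the other largest rises. The other falls were Lct (-2.46), Ndst4 (-2.45), Gm2115 (-2.08), Cabp7 (-1.90), Prss35 (-1.24), Chst9 (-1.24), Fibcd1 (-2.12), Lrrc10b (-1.99) and Drd5 (-1.34). WT 0 h replicate 1 held much of Fibcd1 (41.4 CPM in a group from 3.99 to 41.4 CPM). Without that library Lct (-1.03, adjusted p = 0.0253), Ndst4 (-1.34, adjusted p = 0.00331), Gm2115 (-0.99, adjusted p = 7.34e-05) and Cabp7 (-1.09, adjusted p = 0.00136) were still called at smaller falls, while Fibcd1 (-0.56, adjusted p = 0.147), Lrrc10b (-0.25, adjusted p = 0.686) and Drd5 (0.16, adjusted p = 0.83) were not called. All WT 0 h libraries had hippocampal markers at a mean log2 CPM of 2.82 to 3.61, above the 2.49 to 2.68 of WT at 6 h. In T308A, Gm2115 stood at 4.68 CPM at 0 h and 4.78 CPM at 6 h, and Cabp7 at 3.62 and 3.53 CPM. Hippocampal tissue in the WT 0 h libraries is therefore a possible explanation of these falls, which was not tested. DESeq2 gave no adjusted p for Ndst4 and Gm2115. Mecp2 did not pass (-0.10 ± 0.042, adjusted p = 0.0908), though DESeq2 called it (-0.09, adjusted p = 0.0375).

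In WT at 8 weeks 9 lists passed with the preset correlation and none with an estimated one. Of 26 early response genes 21 rose and 1 fell by either count (adjusted p = 0.396 with an estimated correlation), and of 26 late response genes 24 rose over all genes and 26 over the list alone (adjusted p = 0.252 with an estimated correlation), Bdnf (2.20) and Nrn1 (1.09) among them. Of 25 glutamate receptor genes 12 rose over all genes, and 13 rose and 2 fell over the list alone, with Gria3 (0.49), Grin2a (0.81) and Cacng3 (0.72), and an adjusted p = 0.587 with an estimated correlation. Of 12 glucocorticoid response genes 6 rose by either count, with Zbtb16 (0.96), and an adjusted p = 0.396 with an estimated correlation. Of 15 genes of MeCP2 and its partners 7 rose by either count, with Hdac3 (0.28) and Dnmt1 (0.30), and an adjusted p = 0.263 with an estimated correlation.

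Glial and ribosomal lists leaned down in WT at 8 weeks. Of 16 oligodendrocyte markers 4 fell by either count, with Ermn (-0.90) and Gpr37 (-0.56), and an adjusted p = 0.594 with an estimated correlation. Of 12 astrocyte markers 5 fell by either count and of 12 microglia markers 3, each with an adjusted p = 0.587 with an estimated correlation. Without WT 0 h replicate 1 the calls of Aldoc (from -0.36 to -0.22, adjusted p = 0.0718) and Sox9 (adjusted p = 0.0923), both astrocyte markers, ended. Of 81 ribosomal protein genes 7 fell over all genes and none over the list alone, with an adjusted p = 0.712 with an estimated correlation.

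In T308A VC at 8 weeks, Nptx2 rose from 15.6 ± 1.45 CPM (SD, n = 3) to 157 ± 66.4 CPM (SD, n = 10), by 3.33 ± 0.327 (adjusted p = 1.26e-06). Egr2 rose to 24.8 ± 14.5 CPM (4.20 ± 0.671, adjusted p = 0.000125) and Npas4 from 5.21 ± 1.84 to 43.5 ± 19.7 CPM (3.05 ± 0.399, adjusted p = 1.71e-05). Stc1, a secreted hormone gene, fell from 5.12 ± 0.421 to 1.83 ± 0.569 CPM (-1.48 ± 0.185, adjusted p = 1.09e-05).

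In T308A 1880 genes rose and 1596 fell with light (1989 calls without T308A 0 h replicate 3). Mir212 (3.61), Timp1 (3.25), Inhba (3.15), Ptgs2 (3.07), Fos (3.05), Car12 (3.01) and Fosb (2.97) were the other largest rises. Acot5 (-1.23), Maats1 (-1.17), Pkd1l2 (-1.15), Mndal (-1.13), Gpr1 (-1.12), Rgs22 (-1.11), 4833412C05Rik (-1.08) and Stpg1 (-1.05) fell and kept their calls whichever library was left out. Atp6v1c2 (-1.16) lost its call without T308A 0 h replicate 3 (adjusted p = 0.062). Mecp2 did not change (-0.03 ± 0.038, adjusted p = 0.622).

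Of 26 early response genes 23 rose and 1 fell in T308A over all genes, and 24 rose and 1 fell over the list alone, with Fosl2 (2.27), and an adjusted p = 0.103 with an estimated correlation. Late response genes rose in 25 of 26 cases by either count, with Bdnf (2.60) and Scg2 (1.46), and an adjusted p = 0.0814 with an estimated correlation. Of 12 glucocorticoid response genes 8 rose over all genes and 9 over the list alone, with Mt2 (1.03) and Fkbp5 (0.81), and an adjusted p = 0.102 with an estimated correlation. Of 15 inhibitory markers 6 rose by either count, with Gad2 (0.31), and an adjusted p = 0.692 with an estimated correlation. WT and T308A shared 1193 rises (278.2 for independent lists) and 700 falls (188.8), with 4 and 2 called in opposite directions. WT VC at 4 h in young mice and at 6 h at 8 weeks shared 900 rises (260.1) and 372 falls (155.7), with 12 and 34 in opposite directions.

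In dark-housed mice of 8 weeks, T308A was compared with WT at 0 h. The RIKEN gene 4931440J10Rik (chromosome 14, 62760501 to 62830126) stood at 12.1 ± 1 CPM in T308A and 6.25 ± 0.358 CPM in WT (0.95 ± 0.123, adjusted p = 0.00104; SD, n = 3). Necab2 (chromosome 8, 119446719 to 119472640), a calcium-binding protein of neurons, stood at 14.4 ± 0.844 and 24.5 ± 1.57 CPM (-0.76 ± 0.125, adjusted p = 0.02). Pls3 (chromosome X, 75785653 to 75875182), an actin-bundling protein, stood at 84.3 ± 3.41 and 111 ± 8.02 CPM (-0.40 ± 0.067, adjusted p = 0.02).

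The fourth call at 0 h was Dsc3 (chromosome 18, 19960930 to 20002410), a desmosomal cadherin, at 0.199 ± 0.0374 CPM in T308A and 1.52 ± 0.57 CPM in WT (-2.88 ± 0.502, adjusted p = 0.0274). Its mean was under 1 CPM, so it lay outside the naming rule and was chosen after its values were seen. These 4 were all the calls of 15049 genes tested (1507 at an unadjusted p under 0.05), 1 up and 3 down, while DESeq2 called 7 up and 8 down. With 1 library left out the number of calls ran from 1 to 21. Only 4931440J10Rik kept its call whichever library was left out. Necab2 lost it in 4 of 6 fits, with an adjusted p up to 0.197 without T308A 0 h replicate 3, and Pls3 in 4 of 6, up to 0.247 without T308A 0 h replicate 1. Mecp2 was level (-0.05 ± 0.047, adjusted p = 0.713).

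With the preset correlation 10 lists passed at 0 h, with no member called over all genes. All 12 astrocyte markers were lower in T308A (median -0.225), 5 of them over the list alone, with Aldoc (-0.35) and Gja1 (-0.30), and an adjusted p = 0.216 with an estimated correlation. Of 9 hippocampal markers 8 were lower (median -0.325), 4 of them over the list alone, with an adjusted p = 0.0746 with an estimated correlation. Of these, Fibcd1 stood at 3.36 ± 0.395 CPM in T308A and 17.8 ± 20.6 CPM in WT. Choroid plexus markers (-0.466; 2 of 4 called over the list alone) had an adjusted p = 0.216 with an estimated correlation. Ribosomal protein genes were lower in 80 of 81 cases (median -0.138, Rpl10 -0.26; adjusted p = 0.492 with an estimated correlation). The others were glutamate receptors (0.12), oligodendrocytes (-0.267) and heat shock genes (-0.181), each with an adjusted p = 0.538 with an estimated correlation, inhibitory markers (-0.123) and glucocorticoid response genes (-0.233), each with an adjusted p = 0.39 with an estimated correlation, and oligodendrocyte precursors (-0.24; adjusted p = 0.305 with an estimated correlation).

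**Figure D4:**
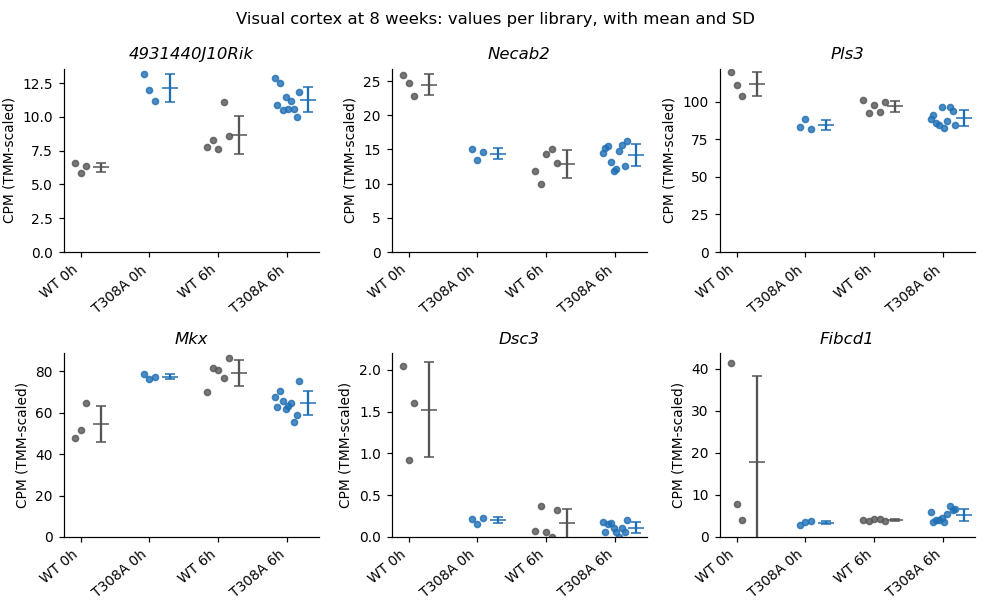
CPM per library (points) with mean and SD for 4931440J10Rik, Necab2, Pls3, Mkx, Dsc3 and Fibcd1 in VC at 8 weeks, in WT and T308A at 0 h and 6 h of light. 4931440J10Rik averages 12.1 CPM in T308A and 6.25 CPM in WT at 0 h, and Fibcd1 spreads from 3.99 to 41.4 CPM among WT 0 h libraries.

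After 6 h of light, edgeR called no gene between T308A and WT (672 at an unadjusted p under 0.05), and DESeq2 called 1. That gene was Cd99l2 (chromosome X, 71420060 to 71492866), an adhesion molecule at 76.1 ± 1.65 CPM in T308A (SD, n = 10) and 68.5 ± 2.27 CPM in WT (SD, n = 5). Its log2 fold change was 0.15 ± 0.032, with an adjusted p = 0.895 in edgeR and an adjusted p = 0.0434 in DESeq2. 4931440J10Rik (0.37 ± 0.082), Mkx (-0.29), Hmgb3 (-0.60) and Tmem196 (-0.27) followed, none passing (adjusted p = 0.895). Without WT 6 h replicate 4, 4931440J10Rik passed (0.48, adjusted p = 0.0361). Mecp2 was level (0.02 ± 0.031, adjusted p = 0.94).

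At 6 h 8 lists passed with the preset correlation, with no member called. Late response genes were higher in T308A in 24 of 26 cases (median 0.177), as were 12 of 14 endothelial and mural markers (0.091), and glutamate receptors had a median of -0.064, each with an adjusted p = 0.788 with an estimated correlation. T308A replicates 5, 8 and 9 stood above the other 7 in light-induced genes, with Nptx2 at 216, 228 and 289 CPM against 94.9 to 173 CPM, and 99.1 to 138 CPM in WT. All 11 heat shock genes were higher (0.193), with an adjusted p = 0.601 with an estimated correlation, the same as for inhibitory markers (0.106). GABA receptors (-0.058) had an adjusted p = 0.482 with an estimated correlation, astrocytes (0.07) 0.761 and ribosomal protein genes (0.046) 0.808.

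Whether light acts differently in T308A was tested by the interaction, which called 2 genes, 1 up and 1 down, of 15049 (1952 at an unadjusted p under 0.05), while DESeq2 called 7 up and 7 down. Necab2 fell with light in WT, from 24.5 ± 1.57 to 12.8 ± 2.01 CPM, and stayed at 14.4 and 14.1 CPM in T308A (0.90 ± 0.153, adjusted p = 0.0388). Mkx (chromosome 18, 6934966 to 7004779), a homeobox gene, rose in WT from 54.7 ± 8.81 to 79.2 ± 6.23 CPM and went from 77.5 ± 1.21 to 64.6 ± 5.74 CPM in T308A (-0.80 ± 0.121, adjusted p = 0.0143). Necab2 lost its call in 11 of 21 fits with 1 library left out, with an adjusted p up to 0.221 without T308A 0 h replicate 2. Mkx lost its call in 5, with an adjusted p up to 0.081 without T308A 0 h replicate 1. Mecp2 did not differ (0.07 ± 0.056, adjusted p = 0.615).

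With the preset correlation 11 lists passed in the interaction, with no member called over all genes. All 12 astrocyte markers were positive (median 0.317, 7 called over the list alone; adjusted p = 0.179 with an estimated correlation), and 80 of 81 ribosomal protein genes (0.185; adjusted p = 0.453 with an estimated correlation, as for glutamate receptors at -0.209). Hippocampal markers had a median of 0.368 (3 called over the list alone; adjusted p = 0.152 with an estimated correlation) and choroid plexus markers of 0.878 (1 called over the list alone; adjusted p = 0.176 with an estimated correlation). Early response genes had a median of 0.205 (1 called over the list alone; adjusted p = 0.666 with an estimated correlation). Inhibitory markers (0.209) had an adjusted p = 0.301 with an estimated correlation, oligodendrocytes (0.268) 0.601, endothelial and mural markers (0.192) 0.456, and oligodendrocyte precursors (0.273) and heat shock genes (0.356) 0.337 each.

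**Figure D5:**
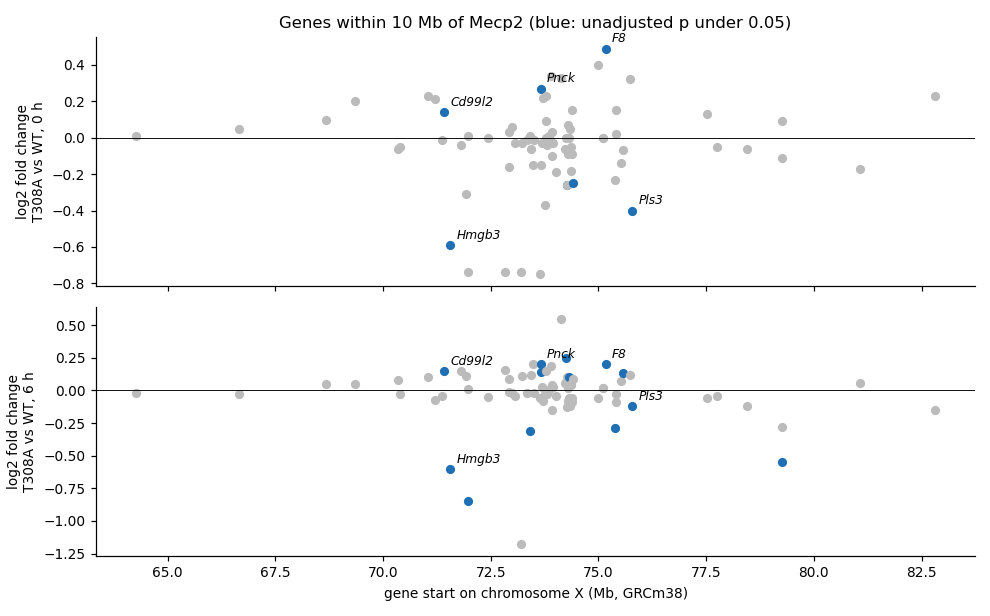
Log2 fold change of T308A against WT at 0 h and at 6 h for genes within 10 Mb of Mecp2 on chromosome X, by position in Mb (GRCm38). Genes with an unadjusted p under 0.05 are blue, and Cd99l2 (0.14 at 0 h, 0.15 at 6 h), Hmgb3 (-0.59, -0.60), Pnck (0.27, 0.20), F8 (0.49, 0.20) and Pls3 (-0.40, -0.12) are labelled.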

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

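The tests of genes near Mecp2, of the T308A calls at 0 h, of the glucocorticoid response genes and of whole animals dealt to light groups were chosen after those results were seen, and the other counts over splits were planned.

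A library stood out when it lay far from the nearest other library of its group on 1 of several measures of depth and marker expression. Across the 126 sets examined 8 did so, where about 6.3 would by chance, so most need no cause. In VC of P30 WT, CTX2 had 20.5 M counts, with the next library at 14.95 M, and its 10 most abundant genes held 4.377% of counts, against 4.967% in the nearest of its group. The QKI libraries CTX1 (4.382%) and CTX3 (4.41%) lay at the same level and CTX1 had 18.9 M counts, so CTX1, CTX2 and CTX3 stood apart together across genotypes. LGN9 of QKI dLGN at 0 h detected 16613 genes, against 17154. LGN7 of WT dLGN at 0 h had the lowest hippocampal markers, at a mean log2 CPM of 2.077 against 2.342. WT 6 h replicate 1 at 8 weeks detected 17326 genes, against 17426, and had the highest blood markers, at 4.762 against 2.416.

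The choroid plexus and ependymal markers of LGN3, QKI dLGN at 4 h, had a mean log2 CPM of 3.206, against 0.3279 in the nearest library. Ttr stood at 741 CPM in LGN3 and between 0.996 and 24.8 CPM in the other dLGN libraries of the light experiment, and its call with light in QKI rested on that library. T308A 6 h replicate 7 at 8 weeks stood out on the same markers at a much lower level, with -0.882 against -1.248.

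The WT light response differed between VC and dLGN for 567 genes. Of 100 splits of the libraries, 4 called as many, the real one included, with 887 in the highest other split. These splits parted the dLGN and VC libraries of an animal, which share an animal number. Among the 35 splits that keep animals whole, 1 called as many, the real one, with 0 in the highest other split. With the animal as a block it was also 1 of 35, with 750 genes in the real split and 2 in the highest other. Without the block, other splits move the light response shared by both tissues into the spread, so that count cannot decide. With the block, each animal's own level takes up the shared response. On that count chance among the animals was set aside.

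The light response differed between T308A and WT at 8 weeks for 2 genes, Necab2 and Mkx. Of 100 splits 5 called as many, the real one included, with 124 in the highest other split, so chance among the libraries was not excluded. At 0 h the 4 calls were reached by 1 of 10 splits, the real one, which is too few splits to decide. Across these comparisons 5 genes were called. The WT 0 h library with the highest hippocampal markers, replicate 1, moved Fibcd1 from -2.386 to -0.827 and Lct from -1.804 to -0.376 when left out. The median absolute log2 fold change of the 5 called genes kept 94.4% of its size (0.763 to 0.72). The other WT 0 h libraries had an excess of these markers too, whose median went from -0.325 to -0.188 only, with C1ql2 at -1.179 and Wfs1 at -0.601. The lowest WT 0 h score was 2.82 and the highest T308A 0 h score 2.48, so hippocampal tissue in the WT 0 h libraries remains a possible explanation. Only 1 of the 5, 4931440J10Rik, stayed called whichever 0 h library was left out, so the small number of libraries remains a candidate explanation for the other 4. An effect of T308A on Necab2 and Mkx stays open.

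Genes near Mecp2 were examined because Cd99l2 and Pls3, both on chromosome X, had small p. Among 77 genes within 10 Mb, 5 had an unadjusted p under 0.05 with the same sign at 0 h and 6 h (Cd99l2, Hmgb3, Pnck, F8 and Pls3), against at most 1 in 184 windows of as many genes elsewhere. This joint count was chosen after a count at 6 h alone, and the values of the genes, had been seen. At 6 h alone 13 window genes had such a p, and 6 of 100 splits gave as many, with 19 in the highest other, so chance was not excluded there. The joint count was reached in 2 of 2000 joint splits, and only 42.9% of window genes had the same sign at both times. Sequence variants near Mecp2 carried over from the strain in which T308A was made are a possible explanation. In the QKI pairs the same count was 0, but the median elsewhere was also 0, so it decides nothing. The correlation of fold changes in the window was 0.102 for T308A, at percentile 99.5 of the windows elsewhere. It was 0.332 in QKI dLGN between P30 and 0 h, also at percentile 99.5, and at percentiles from 1.63 to 87.4 in the other QKI pairs. Changed MeCP2 acting on its neighbours stays open, and an effect of T308A alone was not tested.

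Glucocorticoid response genes rose with light in both tissues. Clock genes also moved, with a mean absolute log2 fold change at percentile 99.8 of matched random lists in the lower of WT dLGN and WT VC. A different time of day at collection is therefore a possible explanation, and the design cannot separate it from light acting on the clock or on stress hormones. Neuronal activity of each tissue alone would make these genes follow the early response genes, whose responses were higher in VC by a median of 0.464, while the median difference of this list was -0.074 with a member SD of 0.427. The bound for that test was reworded after these values were seen. Sgk1 (-0.64, adjusted p = 0.00781) and Zbtb16 (-1.17, adjusted p = 0.00213) responded more in dLGN.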

How the results depend on the processing

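Fits without LGN4 and LGN13 together, without CTX9 of VC, with the animal or an inferred set as a block, and list tests with a block were chosen after seeing the data; the other alternatives were planned. Called genes kept their direction, except Ttr with light in QKI dLGN (3.95 to -0.14 without LGN3) and Drd5. With light in WT at 8 weeks Drd5 went from -1.34 to 0.16 without WT 0 h replicate 1. With the block only the early response list at 6 h reversed (below). No list test left out a library, but without LGN3 the choroid plexus median of the dLGN interaction was -0.102. DESeq2's size factors in place of TMM kept every count on its side and within 1.5 times, from 579 to 577 in WT dLGN and from 4007 to 4027 in WT at 8 weeks, and so did testing without a filter, except in the dLGN interaction. All 208 named-gene results kept their side with other size factors. Slc2a10 in WT dLGN was lost without a filter (adjusted p = 0.0574) and by DESeq2 (adjusted p = 0.0646), which also lost Mir6236 for tissue by light (adjusted p = 0.0564).

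Gene list results depended most on the correlation between genes. With an estimated correlation the number of lists called went from 3 to 0 in dLGN and from 8 to 0 in VC at P30. With light it went from 8 to 4 in WT and from 8 to 5 in QKI dLGN, and from 6 to 2 in WT and 7 to 2 in QKI VC. Between QKI and WT in dLGN it stayed at 0 at 0 h, and went from 1 to 0 at 4 h and from 6 to 0 in the interaction. In VC it went from 6 to 0 at 0 h, 6 to 0 at 4 h and 3 to 0 in the interaction. For tissue by light it went from 2 to 1. At 8 weeks it went from 9 to 0 with light in WT, 4 to 0 with light in T308A, 10 to 0 at 0 h, 8 to 0 at 6 h and 11 to 0 in the interaction. Members of a list vary together between animals, which the estimated correlation takes into account.

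DESeq2 called 1 gene between QKI and WT in dLGN at 4 h and 2 in the dLGN interaction, where edgeR called 0. Without a filter on low counts edgeR also called 2 in that interaction. At 8 weeks DESeq2 (and edgeR) called 15 (4) genes at 0 h, 1 (0) at 6 h and 14 (2) in the interaction. The cause was not tested. The long gene shift of QKI in VC at 4 h was 0.0268 at 60 kb (exact permutation p = 0.0571, two-sided), where 100 kb gave 0.0221. In VC at 0 h, where neither passed, it was -0.0029 at 60 kb and 0.0032 at 100 kb.

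Replicate numbers at 8 weeks did not pair the libraries. The 20 same-numbered pairs had correlations of deviations from -0.355 to 0.251, 4 of them above 0.1, and 0 of 16 libraries correlated best with their own number. With the replicate block the light calls in T308A went from 3476 to 1114, those of T308A at 0 h from 4 to 0 and those of the interaction from 2 to 0. Named genes that lost their call with the block were Lrrc10b (adjusted p = 0.0693) and Drd5 (0.133) with light in WT, Atp6v1c2 (0.157), Pkd1l2 (0.101) and Stpg1 (0.0746) with light in T308A, 4931440J10Rik (0.0743), Necab2 (0.0834) and Pls3 (0.083) at 0 h, and Necab2 (0.197) and Mkx (0.0831) in the interaction. Log2 fold changes of 4931440J10Rik (0.95) and Necab2 (-0.76) at 0 h stayed the same, and the block leaves fewer degrees of freedom. List tests with the block and the preset correlation gained oligodendrocyte precursors (adjusted p = 0.0173) and heat shock genes (0.00349) and lost microglia (0.0635) with light in WT, and gained ribosomal protein genes (0.0246) with light in T308A. They gained early response (0.0363), cortical excitatory (0.0268) and endothelial and mural (0.0406) lists at 0 h, and the thalamic relay list (0.0196) at 6 h. There the early response list turned from higher in T308A (adjusted p = 0.0525) to lower (0.0359). They lost late response (0.933) and endothelial and mural (0.378) lists at 6 h. In the interaction they gained the cortical excitatory list (0.0378) and lost early response (0.507) and endothelial and mural (0.0533) lists. At 8 weeks the block changed no other call of a named gene or list, and no other count by more than 1.5 times. With the replicate block of the animals shared by dLGN and VC, tissue by light went from 567 to 750 genes (498 higher in VC and 252 lower), 556 of them in both fits, none with the opposite sign. Of the named genes only Mir6236 (-2.29, adjusted p = 0.0672) lost its call there, and list tests still called 2 lists.

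The sets inferred at P30 had a mean correlation of deviations of 0.226 in dLGN and 0.178 in VC, against -0.053 and -0.038 for other pairs. Above 0.1 were 6 of 7 and 4 of 7 pairs, and 6 and 5 of 12 libraries correlated best with their own set, a hint from the data. With this replicate block QKI against WT went from 0 to 1 gene in dLGN, Nlrp5-ps (0.70, adjusted p = 0.033), stayed at 0 in VC, and the lists stayed at 3 in dLGN and went from 8 to 10 in VC. There the oligodendrocyte precursors (adjusted p = 0.132) were lost and endothelial and mural markers (0.0151), GABA receptors (0.0332) and heat shock genes (0.0332) gained. In the light experiment the mean was -0.001 in dLGN and 0.035 in VC, and 2 and 6 of 16 libraries correlated best with their own set. With that replicate block light called 564 genes in WT and 1029 in QKI dLGN, and 3048 and 2834 in VC, and the contrasts with a genotype term stayed at 0, Sgk1 at 4 h in dLGN included (adjusted p = 0.365). Mir6236 in WT (adjusted p = 0.0554) and Ttr (0.276) and Tnfsf10 (0.0547) in QKI dLGN lost their calls with light, and the lists of the dLGN interaction went from 6 to 3, without thalamic relay (0.0644), microglia (0.0644) and choroid plexus (0.0908) markers. Gained were clock genes with light in WT dLGN (0.0413), meningeal fibroblasts with light in WT VC (0.038) and microglia in VC at 0 h (0.04).

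With 1 library left out, the light calls ranged from 360 (without LGN16) to 592 in WT dLGN, from 736 to 1060 in QKI dLGN, from 2028 to 3457 in WT VC and from 2005 to 2688 in QKI VC. The dLGN interaction ranged from 0 to 2 (without LGN14 or LGN8), QKI in VC at 4 h from 0 to 3 (without CTX2), and tissue by light from 428 to 936 (without CTX6). At 8 weeks the range was 2356 (without WT 0 h replicate 1) to 3704 with light in WT and 1989 (without T308A 0 h replicate 3) to 3895 in T308A. T308A against WT ranged from 1 (without any single T308A library) to 21 (without WT replicate 3) at 0 h, from 0 to 1 (without WT replicate 4) at 6 h, and from 0 (without WT 0 h replicate 1 or any single T308A 0 h library) to 11 (without WT 0 h replicate 3) in the interaction. The cause was not tested. The calls kept whichever library was left out were 286 of 579, 529 of 1049, 1627 of 2941 and 1534 of 2795 with light in WT and QKI dLGN and WT and QKI VC, 330 of 567 for tissue by light, and 1790 of 4007 and 1463 of 3476 at 8 weeks. Without LGN4 and LGN13 light called 509 genes in WT and 805 in QKI dLGN, and without CTX9, which had the highest Wfs1, the QKI contrast of VC at P30 still called 0.

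Small changes could go without a call. The self-test at 1.5-fold recovered 70.1% of changed genes between QKI and WT in dLGN at 0 h, 71.6% in VC at 4 h, 64.2% for T308A at 0 h and 61.2% in the interaction at 8 weeks, so genes without a call may still have changed by that much.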

Other observations

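Of the tests here, those of the size of the light response and the counts over other splits were planned, and those of the reproducibility of QKI fold changes were chosen after the counts of 0 had been seen.

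Genes of the circadian clock moved with light in both directions. Per2 rose in WT dLGN (0.88, adjusted p = 0.000122), WT VC (1.12, adjusted p = 5.42e-05) and WT VC at 8 weeks (0.78), and Dbp (-0.83, adjusted p = 4.08e-05) and Nr1d1 (-0.74, adjusted p = 9.55e-05) fell in WT VC. Tef fell in WT at 8 weeks (-0.64, adjusted p = 5.92e-06). Of 16 clock genes 7 rose and 6 fell in WT VC by either count, with an adjusted p = 0.936 with an estimated correlation for the list, whose test looks for a shift in 1 direction. In WT at 8 weeks 8 rose and 5 fell over all genes (adjusted p = 0.799 with an estimated correlation).

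Some genes of brain vessels moved with light, without a shift of the list. Of 14 endothelial and mural markers 2 rose and 1 fell in WT dLGN over all genes, and 3 rose and 2 fell over the list alone (adjusted p = 0.93 with an estimated correlation). In WT VC 2 rose and 4 fell by either count (adjusted p = 0.936 with an estimated correlation). Slc2a1, the glucose transporter of the blood-brain barrier, rose in WT dLGN (0.84 ± 0.105, adjusted p = 3.11e-05) and WT VC (0.92, adjusted p = 2.46e-06), and Ly6c1 rose in WT dLGN (0.76, adjusted p = 0.00187). The tight junction gene Cldn5 fell in WT dLGN (-0.70, adjusted p = 0.00436) and WT VC (-0.50). Among microglia markers 4 of 12 fell in WT VC, P2ry12 (-0.45, adjusted p = 0.000774) among them, with an adjusted p = 0.845 with an estimated correlation.

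Whether QKI or T308A changes the size of the whole light response was tested with the score per library, by two-sided exact permutation tests. In dLGN the score rose by 0.68 in WT and 0.796 in QKI, a difference of 0.116 (exact permutation p = 0.191, adjusted over 3 tests 0.33). In VC it rose by 0.746 and 0.743, a difference of -0.003 (exact permutation p = 0.972, adjusted 0.972). At 8 weeks it rose by 0.397 in WT and 0.514 in T308A, a difference of 0.118 (exact permutation p = 0.22, adjusted 0.33). T308A 6 h replicates 5, 8 and 9 scored 1.714, 1.758 and 1.85, above the other 7 (1.3 to 1.52) and WT (1.404 to 1.494). No change was detected, which leaves small ones open.

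Whether QKI fold changes recur between P30, 0 h and 4 h was tested by their mean correlation across genes, with QKI and WT labels permuted within each experiment. In dLGN the mean was 0.058 (one-sided exact permutation p = 0.147) and in VC 0.005 (one-sided exact permutation p = 0.405). A shared QKI effect was not detected. How large an effect this test could miss was not assessed, so one stays open.

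The number of genes called was recounted after dealing the same libraries into other groups of the same sizes. For light in WT dLGN 1 of 35 splits, the real one, called as many genes, with 18 in the highest other split, and 1 of 35 in QKI dLGN, with 2. In VC it was 1 of 35 in WT, with 257, and 1 of 35 in QKI, with 0. At 8 weeks it was 1 of 56 in WT, with 0, and 1 of 100 in T308A, with 2506. Chance among the libraries was thus set aside for light, while the cause of the counts of 2506 and 257 in other splits was not tested.

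Where no gene was called, every split reaches that count, so these counts say nothing about the real grouping. They were 100 of 100 in dLGN and in VC at P30, with 44 and 111 genes in the highest other split. They were 35 of 35 in dLGN at 0 h and at 4 h, with 0 and 2, and 35 of 35 in VC at 0 h and at 4 h, with 0 and 404. They were 100 of 100 in the interactions in dLGN and VC, with 19 and 40, and 100 of 100 for T308A at 6 h, with 169. Splits with more calls than the real grouping mark other differences among the libraries, whose cause was not tested.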
